A study of Homo sapiens with 4 samples.

How the data were processed

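Per the labels' protocols, RNA was extracted from AMO1 cells with a column kit and libraries were made with a SMARTER mRNA-Seq kit. The genome build was hg38, per the submitters' processing notes, and the aligner, the counting program, the use of strand and the authors' statistical test are not given in the sources used here. The 4 libraries were mapped to their columns by the short names in the labels, 2 of the empty vector (EV) and 2 of PHF19 overexpression (PHF19_OE). Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

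The deposited table gives, per the file headers, raw read counts per gene and library, normalized values, FPKM, group means and, for the comparison of PHF19_OE with EV, a log2 fold change, a p-value and an adjusted p-value. It holds 1232 genes, and the highest p-value in it is 0.0499, so it contains only genes the authors selected. The deposited normalized values (a signal scale of counts divided by a factor per library) equal count over 1.26 for EV replicate 1, 1.02 for EV replicate 2, 0.832 for PHF19_OE replicate 1 and 0.977 for PHF19_OE replicate 2. The deposited FPKM values, with the deposited gene lengths and counts, return the library totals of 35258920, 29461022, 23835805 and 28156519 reads; the listed genes hold 7.07%, 4.03%, 4.38% and 3.97% of them. Benjamini-Hochberg adjustment of the deposited p-values over 16881 genes returned 1208 deposited adjusted values within a relative tolerance of 1e-06, and the other 24 have an adjusted p of 1. Of these 16881 genes 7.16% had a p under 0.05, 1208 against 844 with no effect. All 1232 gene coordinates equal those of a GENCODE annotation of the same build. A spreadsheet had turned 3 symbols into dates, and they were restored from the gene identifiers.

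Because the table holds selected genes, the authors' number of higher and lower genes at an adjusted p of 0.05 is the main result, as laid down for that case before the data were examined, and fold changes keep the authors' size factors. The counts were tested again among the listed genes only, on the same samples that selected them, so these counts are no independent evidence and no share of all genes. That test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors from the listed genes, library totals as above and low counts removed by filterByExpr, which left 1066 genes. TMM on the listed genes shifted the median log2 fold change by 0.59 and DESeq2's size factors on the listed genes by 0.94 relative to the authors' scaling; directions given in the text follow the authors' scaling, and among list members ICAM3 and NDRG1 changed sign under the latter. Counts were also simulated for the 1232 genes of this comparison (10 runs, 200 genes changed). On them edgeR recovered 22.4% of 4-fold and 82.0% of 16-fold changes, with 4.70 false calls among 109 on average. DESeq2 1.42.0 recovered 41.9% and 92.6%, with 18.0 false calls among 152.5. The simulation gave both groups the same spread and adjusted over the simulated genes alone. In the data the EV pair was wider than the overexpressing pair, so these rates do not carry over to the calls reported here.

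Means and SDs are over the 2 normalized counts of a group. Distances of over 2-fold between or from single libraries, where counted over called or listed genes, Pearson's r and median log2 differences from an EV library use log2 of the normalized count plus 1, which understates the change of low genes. A gene with 0 counts in a group was set against a floor of 3 counts over the group, and one with 1 to 3 counts is given as a ratio of counts with an exact 95% interval. An exact permutation test of 2 against 2 cannot go below 0.333 and was not used. Named genes follow a rule fixed before the data were examined: PHF19 and the listed members of the PRC2 and BCL2 lists, the 6 coding genes with the largest rise and the 6 with the largest fall past 0.05 with at least 50 normalized counts in the higher group and no overlap of the groups, and up to 4 members past the threshold from each list. Some genes that meet this rule are not reported here. All other genes named were chosen after their values were seen, because a count was small, to show EV replicate 1, or as further MHC class II members (HLA-DRA, HLA-DMA, HLA-DMB and CIITA). The 26 lists were also fixed beforehand. They hold 733 entries, in which a gene on more than 1 list counts once for each. List sizes count names, so MS4A1 and CD20, CXCL8 and IL8, and DDX58 and RIGI, each pair naming the same gene, are counted separately. Each list with at least 5 listed members had its higher and lower members compared with the other listed genes by a two-sided Fisher's exact test, adjusted over 10 lists, in place of a ranked set test, which needs all genes. The hypergeometric test of members past 0.05 takes the 16881 adjusted genes as background and counts every list gene in it, which makes it conservative where some were not tested. It also counts genes as independent, which genes measured in the same libraries are not, so its p-values can overstate the evidence. Overlapping and antisense genes, and genes with near-identical copies such as the HLA-DR beta genes, are uncertain.

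Alternatives were DESeq2's size factors and its test, no filter and a mean of at least 50 counts, the replicate number as a block, each replicate left out, coding genes only, an adjusted p of 0.01 and an absolute log2 fold change of at least 1. The authors' size factors, library totals alone, adjustment over 16881 genes and the hypergeometric test were added after the data were seen. Statistics and plots outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.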

Results

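RNA sequencing was carried out on AMO1 cells, an established human multiple myeloma line, that had received a lentiviral vector. One group carried the empty vector (EV) and the other overexpressed PHF19, a Polycomb-like protein that associates with Polycomb repressive complex PRC2. Each group held 2 libraries, so n = 2 for every mean below. The EV libraries held 35258920 and 29461022 counted reads and the PHF19-overexpressing libraries 23835805 and 28156519. The deposited table lists the 1232 genes with a p-value under 0.05 in the authors' test, together with the counts of each library. Genes outside it did not reach that value or were not tested, so that nothing is said here about their levels. The comparison asks which transcripts differed between PHF19-overexpressing and empty vector cells.

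PHF19 itself was higher in both overexpressing libraries than in both EV libraries. Its normalized count was 9223 ± 631 (SD, n = 2) in the overexpressing cells and 3174 ± 1883 (SD, n = 2) in the EV cells, a 2.91-fold difference of means. EV replicate 1 stood at 1842 and EV replicate 2 at 4506, so that the overexpressing mean was 5.01-fold above the first and 2.05-fold above the second. The gene lies at chromosome 9, 120855652 to 120894896, on the minus strand of hg38, and the count does not separate transgene from endogenous reads. In the authors' deposited table its log2 fold change was 1.54 with an adjusted p of 0.0897, which missed 0.05, and adjusted over the list alone (the 14 PRC2 subunits and accessory proteins) it was 0.0259. EdgeR's quasi-likelihood test with all libraries gave an unadjusted p of 0.0263 and missed 0.05 once adjusted over 16881 genes. Without 1 EV library the test has no EV spread to use, so only the folds against each EV library are given. PHF19 was the sole PRC2 list member in the table. Of the 20 PRC1 and H3K27 demethylase genes, CBX2 and RNF2 were listed and neither passed 0.05 (CBX2 passed when adjusted over the list alone).

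Overexpressing cells differed from EV cells in 293 genes at an adjusted p under 0.05 in the authors' deposited table, of which 112 rose and 181 fell. MHC class II genes, the surface receptors CD300A and PDCD1 and the plasma cell antigen CD38 fell, whereas ARHGAP15, NSG1, OAS3 and the B cell receptor chain CD79B rose. The median deposited log2 fold change was 3.51 among the called genes that rose and -3.48 among those that fell. Calling genes from 2 libraries per group favours large changes, so these medians do not describe the size of change in general. Both overexpressing libraries had 0 counts for 21 of the 293 genes, and both EV libraries for 18. The groups did not overlap in 289 of the 293, which selection by this same comparison favours, and the exceptions were FRMPD4, NSG2, HOPX and ERICH2, each high in EV replicate 1 alone. On the scale of log2 of the normalized count plus 1, 284 of the 293 lay over 2-fold from each EV library taken singly, which the selection also favours. The other 9 did so only from EV replicate 1 (276 and 15 with a pseudocount of 5). Of all 1232 listed genes, 741 lay over 2-fold from each EV library, 404 only from EV replicate 1, 52 only from EV replicate 2 and 35 from neither. EGR2, among the 9, was 2.03-fold higher in EV replicate 2 than in overexpressing cells on normalized counts with none added. EdgeR's quasi-likelihood test on the listed counts, with the authors' size factors and adjusted over 16881 genes, called 0 genes (522 at an unadjusted p under 0.05). DESeq2 called 134, of which 122 were among the 293. Both estimated the spread from the listed genes alone, so these are not the numbers that a test of all genes would give. Higher genes made up 38.2% of the authors' calls. With edgeR adjusted over the listed genes alone, they made up 51.7% of 149 calls with the authors' size factors and 64.5% of 197 with TMM factors from the listed genes. With DESeq2 on the listed genes and the authors' size factors they made up 34.0% of 365.

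**Figure D1:**
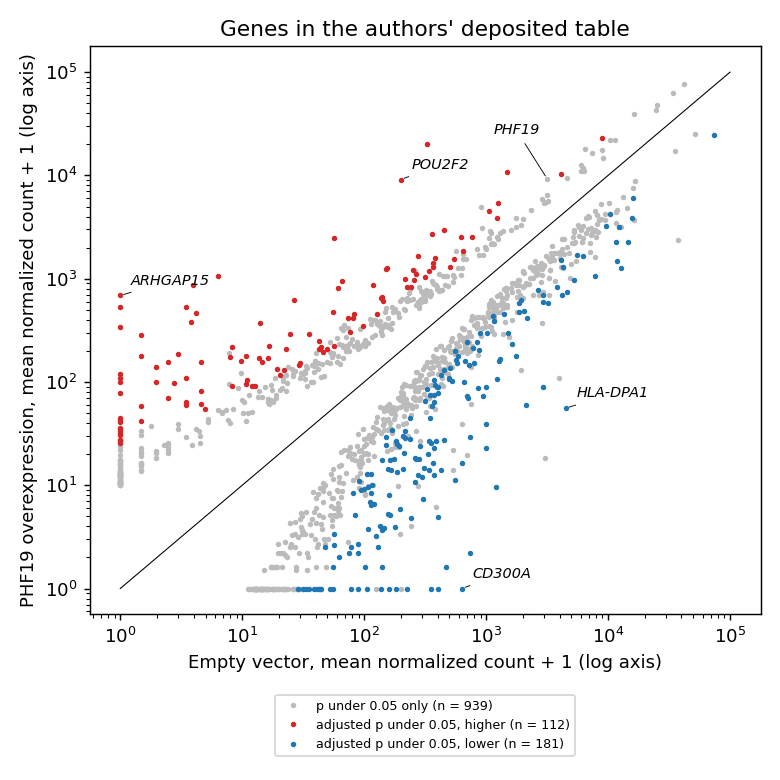
Mean normalized read count plus 1 in EV cells (x, log axis) and in PHF19-overexpressing cells (y, log axis) for the 1232 listed genes, 1 point per gene and the mean of 2 libraries per group, with the line of equality. Red points mark the 112 genes that rose and blue points the 181 that fell at the authors' adjusted p under 0.05; grey points, PHF19 among them, had only an unadjusted p under 0.05.

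The 6 coding genes with the greatest rise were nearly silent in EV cells. ARHGAP15, a GTPase-activating protein (chromosome 2, 143091362 to 143768352), had 0 counts in both EV libraries and a normalized count of 687 ± 34.8 (SD, n = 2) in overexpressing cells, at least 522-fold higher against a floor of 3 counts over the EV group. NSG1, a neuronal endosomal protein, reached 530 ± 88.4 (SD, n = 2; at least 408-fold higher), OAS3, an interferon-induced oligoadenylate synthetase, 342 ± 9.79 (SD, n = 2; at least 260-fold), SLC12A8 108 ± 16.7 (SD, n = 2; at least 82.9-fold) and TUSC3, an oligosaccharyltransferase component, 99.3 ± 7.35 (SD, n = 2; at least 75.4-fold), all from 0 EV counts. ROBO2, a receptor for SLIT proteins, had 1 EV count and 272 and 230 counts in the overexpressing libraries, a ratio of 634 with a 95% counting interval of 113 to 25091.

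The greatest falls mirrored this. CD300A, an inhibitory receptor of leukocytes (chromosome 17, 74466399 to 74484796), went from 631 ± 201 (SD, n = 2) to 0 counts, at least 390-fold lower. TMEM173, which encodes the innate immune adaptor STING, stood at 354 ± 106 (SD, n = 2) in EV cells, PDCD1, which encodes the checkpoint receptor PD-1, at 181 ± 32.4 (SD, n = 2), the lipase gene LIPH at 157 ± 149 (SD, n = 2) and the acyltransferase gene LPCAT2 at 136 ± 87.0 (SD, n = 2). All 4 had 0 counts in overexpressing cells, which puts TMEM173 and PDCD1 at least 219- and 107-fold lower. Adjusted p-values of these 11 genes ran from 2.37e-12 for ARHGAP15 to 9.09e-06 for TUSC3 in the authors' deposited table, and the intervals and floors cover counting error only.

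MHC class II genes, which present peptides to helper T cells, formed a uniform group. Of the 13 on the list fixed beforehand, 11 were in the table, all lower in overexpressing cells, and 8 fell at the adjusted p of 0.05 (11 when adjusted over the list alone). HLA-DPA1 (chromosome 6, 33064569 to 33080775) fell from 4497 ± 728 to 54.7 ± 9.43 normalized counts (SD, n = 2 each), 82.2-fold. HLA-DRA fell 10.2-fold, from 12867 ± 2184 to 1264 ± 416 (SD, n = 2 each), HLA-DMA 3.42-fold and the invariant chain gene CD74 3.02-fold, from 74063 ± 11027 to 24512 ± 175 (SD, n = 2 each). HLA-DPB1 stood at 538 and 1354 in the EV libraries and at 72.4 ± 29.3 (SD, n = 2) in overexpressing cells, 13.1-fold lower (7.43-fold without EV replicate 2), and HLA-DMB at 140 and 292 against 27.7 ± 8.59 (SD, n = 2), 7.81-fold lower (5.06-fold without EV replicate 2). HLA-DQB1 had 0 counts in overexpressing cells and was at least 27.2-fold lower (15.9-fold without EV replicate 1). HLA-DRB1 fell 41.4-fold, a value left uncertain because HLA-DR beta genes share near-identical sequence and alleles can differ from the reference. The transactivator gene CIITA, at 1422 ± 1029 (SD, n = 2) in EV and 380 ± 220 (SD, n = 2) in overexpressing cells, did not pass. In the authors' deposited table HLA-DPA1 had a log2 fold change of -6.36 and an adjusted p of 9.02e-48. The split of higher and lower members did not pass against that of all listed genes (two-sided Fisher's exact test, raw p = 0.00942, adjusted over 10 lists 0.0942). By that test the adjusted p was 0.0366 without EV replicate 1 and ranged from 0.0366 to 0.202 over the 7 alternatives. Because 63.6% of all listed genes were lower, even 11 of 11 lower members, the most uneven fall possible, missed 0.05. The miss therefore does not show that the list split like the other listed genes. A hypergeometric test of members past 0.05, chosen after the values were seen, gave an adjusted p of 2.32e-10 over 26 lists, with 8 members where 0.226 were expected. That test counts the members as independent, which genes measured in the same libraries are not, so its p can overstate the evidence. Of the 11 members, HLA-DQB1 was over 2-fold higher in EV replicate 1 than in EV replicate 2, and CIITA, HLA-DPB1 and HLA-DMB were over 2-fold higher in EV replicate 2. Some listed markers of other cell types were lower too: the T cell markers CD3E (50.7 and 26.4 in EV against 0 and 4.09 in overexpressing libraries) and TRAC (34.9 and 13.7 against 2.40 and 1.02), the myeloid marker ITGAM (94.3 and 15.6 against 0 in both) and the epithelial marker CDH1, while the erythroid marker HBB was higher.

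**Figure D2:**
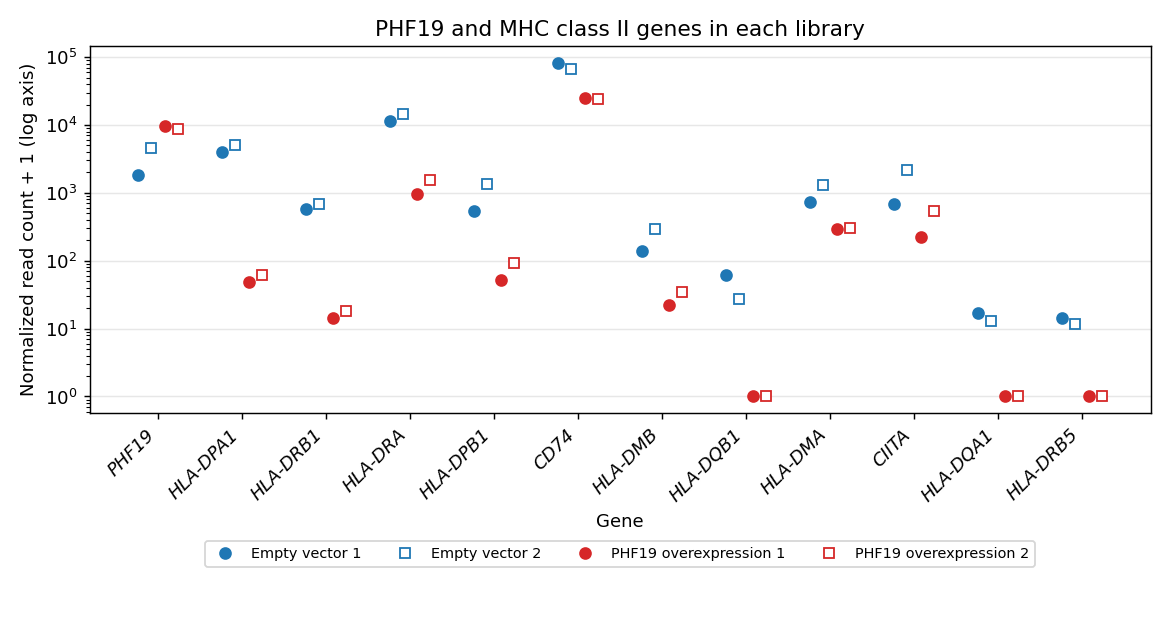
Normalized read count plus 1 (log axis) of PHF19 and of the 11 listed MHC class II genes in each of the 4 libraries, 1 point per library, blue for empty vector and red for PHF19 overexpression. HLA-DPA1 sat at 3982 and 5011 in EV and at 48.1 and 61.4 in overexpressing libraries; CIITA, HLA-DQA1 and HLA-DRB5 did not pass the authors' adjusted p of 0.05.

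B cell genes moved in both directions, and the plasma cell gene that passed fell. Of 27 B cell genes, 6 were listed and 4 passed, 3 lower and 1 higher (5 adjusted over the list alone; hypergeometric adjusted p = 0.0148). CD79A, a chain of the B cell receptor complex, fell from 211 and 65.5 in the EV libraries to 2.65 ± 2.04 (SD, n = 2), 52.3-fold (24.7-fold without EV replicate 1 and 79.9-fold without EV replicate 2), while CD79B, its partner chain, rose 4.81-fold from 251 ± 49.9 to 1208 ± 118 (SD, n = 2 each). The tetraspanin gene CD37 fell 40.0-fold, and CD74 is shared with the class II list. Of 26 plasma cell genes, 5 were listed and 1 passed (3 adjusted over the list alone): CD38 fell 3.44-fold, from 2683 ± 770 to 781 ± 171 (SD, n = 2 each). In the authors' deposited table the adjusted p was 0.00359 for CD38 and 1.60e-05 for CD79B. Of 27 myeloma oncogenes, 5 were listed and 1 passed (2 adjusted over the list alone).

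Developmental transcription factors were mostly outside the table: 5 of 71 were listed and 3 passed (3 adjusted over the list alone). MEIS2 rose 3.57-fold from 96.2 ± 28.5 to 344 ± 37.6 (SD, n = 2 each). GATA3 fell from 76 and 203 counts in the EV libraries to 0 and 3, a ratio of 73.6 with a 95% counting interval of 24.9 to 359 (120 without EV replicate 1 and 36.3 without EV replicate 2). The homeobox list's split did not pass (adjusted p = 0.219, Fisher's exact test).

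Most listed cytokine signalling genes were lower in overexpressing cells, as were 63.6% of all listed genes, and many were highest in EV replicate 1. Of the listed members, 8 of 10 JAK-STAT and growth factor genes and 6 of 7 NF-kB targets, cytokines and chemokines were lower. Neither split passed against that of all listed genes (Fisher's exact test, adjusted p = 0.618 for each). Of 38 JAK-STAT and growth factor genes, 10 were listed and 4 passed (9 adjusted over the list alone; hypergeometric adjusted p = 0.0358): JAK3, SOCS1 and the MAP kinase phosphatase gene DUSP4 fell and ETV4 rose. DUSP4 stood at 21006 and 8238 in the EV libraries and at 2241 ± 17.1 (SD, n = 2) in overexpressing cells, JAK3 at 3930 and 1917 against 700 ± 132 (SD, n = 2), and SOCS1 at 1281 and 138 against 68.4 ± 17.1 (SD, n = 2). ETV4 rose from 7.17 ± 2.30 to 91.4 ± 52.6 (SD, n = 2 each). In this list 7 of 10 members were over 2-fold higher in EV replicate 1 than in EV replicate 2. In log2 of the normalized count plus 1, the median difference of overexpressing cells was -2.26 against EV replicate 1 and -0.544 against EV replicate 2. On that scale 5 members lay over 2-fold from both EV libraries and 5 only from EV replicate 1. Of 33 NF-kB targets, cytokines and chemokines, 7 were listed and 3 fell (5 adjusted over the list alone): TNFAIP3, an inhibitor of NF-kB, fell 2.93-fold, to 3327 and 3218 in the 2 overexpressing libraries, as did HGF and CXCL10. HGF stood at 463 and 98.8 in the EV libraries and at 16.9 ± 5.04 (SD, n = 2) in overexpressing cells, 16.6-fold lower (5.86-fold without EV replicate 1 and 27.4-fold without EV replicate 2), and CXCL10 at 18.2 and 203 against 5.90 ± 3.24 (SD, n = 2), 18.8-fold lower (34.5-fold without EV replicate 1 and 3.09-fold without EV replicate 2).

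Listed interferon-stimulated genes were mostly lower, but their split did not pass against that of all listed genes (Fisher's exact test, adjusted p = 0.219). Of 46, 12 were listed, 11 lower and OAS3 higher, and 4 passed (4 adjusted over the list alone), OAS3 and the lower genes MX1, MX2 and EPSTI1. MX1, an antiviral GTPase, stood at 2240 and 351 in the EV libraries and at 165 ± 50.1 (SD, n = 2) in overexpressing cells, MX2 at 209 and 18.6 against 7.43 ± 5.41 (SD, n = 2), and EPSTI1 at 528 and 236 against 91.8 ± 1.02 (SD, n = 2). EV replicate 1 exceeded EV replicate 2 by over 2-fold in 9 of the 12, and the median difference of overexpressing cells, in log2 of the normalized count plus 1, was -3.51 against EV replicate 1 and -1.01 against EV replicate 2 (-2.40 and -0.946 with a pseudocount of 5). Immediate early and heat shock genes, which respond within minutes to stress or handling, were also highest in EV replicate 1. Of 21, 6 were listed, and all 6 were over 2-fold higher in EV replicate 1 than in EV replicate 2. EGR2 and HSPA6 fell (2 adjusted over the list alone): EGR2 stood at 478 and 7.82 in the EV libraries and at 3.85 ± 0.345 (SD, n = 2) in overexpressing cells, HSPA6 at 586 and 35.2 against 13.6 ± 14.1 (SD, n = 2). FOSB, at 6029 and 9.78 in the EV libraries, did not pass.

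**Figure D3:**
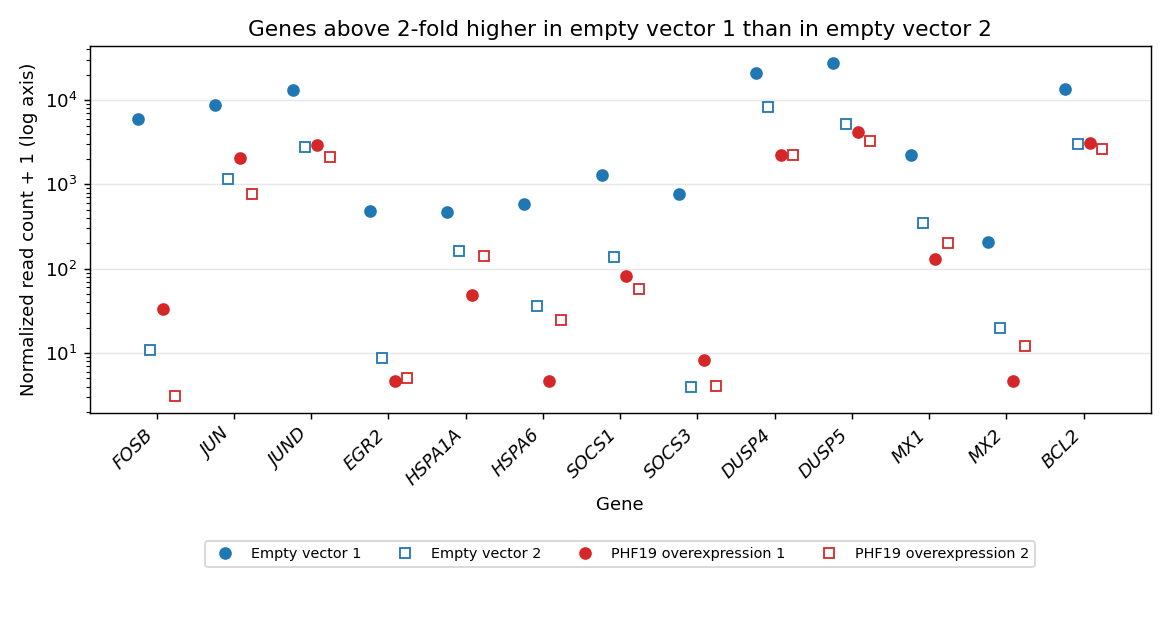
Normalized read count plus 1 (log axis) of 13 stress, signalling and interferon genes, chosen because EV replicate 1 exceeded EV replicate 2 by over 2-fold, in each of the 4 libraries, 1 point per library, blue for empty vector and red for PHF19 overexpression. FOSB stood at 6029 in EV replicate 1 and at 9.78 in EV replicate 2, and BCL2 in EV replicate 2 lay beside the overexpressing libraries.

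Few genes of the remaining lists were in the table. ITGA6, the laminin receptor integrin alpha chain, rose 2.83-fold to 1534 ± 62.1 (SD, n = 2), while ITGAM and the cadherin gene CDH1 fell, so that 3 of 6 listed adhesion genes of 42 passed (4 adjusted over the list alone). Both are also markers of other cell types. Of 21 myeloid and erythroid markers, ITGAM and HBB were listed and both passed (2 adjusted over the list alone), HBB, a globin gene, rising from 58.6 and 24.4 in the EV libraries to 207 ± 37.5 (SD, n = 2), 4.98-fold (8.45-fold without EV replicate 1). CDH1 was the sole listed gene of 18 fibroblast, endothelial and epithelial markers (1 adjusted over the list alone). CD3E and TRAC were the listed T and NK cell markers of 18, both lower (values above), and neither passed, over all genes or adjusted over the list alone. Of 29 glycolysis and hypoxia genes 4 were listed, and PFKFB4 passed (2 adjusted over the list alone), falling from 832 and 328 in the EV libraries to 152 ± 14.8 (SD, n = 2), 3.82-fold (2.16-fold without EV replicate 1). BCL2, the sole listed gene of 16 in its family, stood at 13591 and 3002 in the EV libraries and at 2859 ± 324 (SD, n = 2) in overexpressing cells and did not pass, over all genes or adjusted over the list alone. No member passed, over all genes or adjusted over the list alone, among CDK inhibitors and p53 targets (2 of 25 listed), the unfolded protein response (2 of 31), MHC class I and antigen processing (1 of 18), cholesterol and fatty acid synthesis (1 of 30) or mitochondrially encoded and histone genes (4 of 26, all higher). None of 42 cell cycle genes, 32 MYC and ribosome biogenesis targets, 27 proteasome subunits or 22 drug transporters and detoxification genes was in the table. By Fisher's exact test the split passed an adjusted p of 0.05 in none of the 10 lists with at least 5 listed members. Short lists could not pass in the lower direction: immediate early and heat shock genes, 6 of 6 lower, had a raw p of 0.0922. The misses therefore do not show that these lists split like the other listed genes. The hypergeometric test, which counts genes as independent, passed in 3 lists.

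The EV libraries differed from each other more than the overexpressing ones did. Among 1015 listed genes with a mean normalized count of at least 20, 55.3% lay over 2-fold apart in the EV pair and 15.9% in the overexpressing pair (52.9% and 10.4% with a pseudocount of 5 in place of 1). Across all 1232 listed genes, which are not independent replicates, Pearson's r of log2 values was 0.874 within EV and 0.968 within overexpressing cells. Between groups it ran from 0.569 for EV replicate 1 to 0.755 for EV replicate 2. The genes were selected for a difference between the groups, which lowers r between groups, so these values do not describe all genes. Neither pair agreed within counting error (chi-square per degree of freedom 364 for EV and 42.8 for overexpression), which argues against 1 library deposited under 2 names but does not show separate cultures. The 4 libraries were kept as separate samples, as labelled.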

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

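The adjustment over 16881 genes, the authors' size factors and library totals alone were chosen after seeing the data. The 293 genes of the authors' test became 185 at an adjusted p under 0.01 and were 252 among coding genes. They stayed 293 with a minimum absolute log2 fold change of 1, which all of them already met, so that setting could not test the count. On the listed counts with adjustment over 16881 genes, edgeR's quasi-likelihood test called 0 (522 at an unadjusted p under 0.05) and DESeq2 134. Both estimated the spread from the listed genes alone, so neither is a recount over all genes, and the cause of the difference was not tested. Among the listed genes alone edgeR called 197. It called 223, 149 and 139 with DESeq2's size factors, the authors' size factors and library totals, 40 with no filter on low counts, 40 with a mean of at least 50 counts and 130 among coding genes (fewer genes tested), and DESeq2 called 365. Higher genes made up 64.5% of the 197, and 72.6%, 51.7% and 51.1% under those other 3 scalings. They made up 34.0% of DESeq2's 365, with the authors' size factors, so the balance differed by test as well as by scaling.

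Leaving out 1 library moved the 197 to between 54 and 778: 617 without EV replicate 1, 778 without EV replicate 2, 54 without PHF19_OE replicate 1 and 66 without PHF19_OE replicate 2, the lone library being assumed to vary like the other group. Adjusted over 16881 genes these were 346, 541, 13 and 14. Removing either EV library takes away the EV spread, which was the wider. With the replicate block 435 were called among the listed genes and 140 over 16881. Differences between replicates correlated at 0.293 between the groups across genes, but the labels give no shared day or culture, so the samples share only a number.

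PHF19 was higher under all 10 alternatives. With all 4 libraries edgeR's test passed 0.05 over 16881 genes only with the replicate block (log2 2.24, adjusted p = 0.0197). When 1 library was left out, log2 values ran from 1.22 to 3.68, and no p-value is given because 1 group then has no spread. Those fits used TMM factors from the listed genes, which shifted the median log2 fold change by 0.401 to 1.09 relative to the authors' scaling. On the authors' scaling the overexpressing mean was 5.01-fold above EV replicate 1 and 2.05-fold above EV replicate 2. The number of lists whose split passed 0.05 was 0 under 6 alternatives and from 0 to 1 when 1 library was left out. The 1 was MHC class II without EV replicate 1. A set test with an estimated correlation was not run because it needs all genes, and the planned pseudocounts and value filters did not apply to the tests of counts. For the values per library on the log2 scale, pseudocounts of 0.5 and 5 in place of 1, added after seeing the data, gave 284 and 276 called genes over 2-fold from each EV library and 9 and 15 from EV replicate 1 alone. The share over 2-fold apart was 56.0% and 52.9% in EV and 16.3% and 10.4% in overexpressing cells. Having 2 libraries per group and 0 to 3 counts in the lower group limits the folds of the strongest genes to bounds.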

Other observations

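The genes and gene families of this part were chosen after their values were seen, as were the tests of a mixed library, of a graded response, of expression level and of chromosome 19. POU2F2, a B cell transcription factor, rose from 199 ± 29.3 to 9121 ± 98.1 normalized counts (SD, n = 2 each), while MEF2C, another lymphoid transcription factor, fell from 11594 ± 2164 to 2247 ± 233 (SD, n = 2 each). CD70, the ligand of CD27, rose from 358 ± 54.4 to 2735 ± 147 and IL27RA, a cytokine receptor chain, from 153 ± 92.7 to 1267 ± 139 (SD, n = 2 each). WNT5A rose from 150 ± 130 to 1233 ± 286 and the proteoglycan gene GPC1 from 64.3 ± 5.83 to 951 ± 4.73 (SD, n = 2 each). The authors' deposited table gives POU2F2 an adjusted p of 2.67e-45, MEF2C 1.75e-07, CD70 2.59e-11, IL27RA 2.97e-06, WNT5A 0.000330 and GPC1 6.20e-16.

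TLR7, a sensor of single-stranded RNA, fell from 107 ± 65.2 to 2.74 ± 0.471, LGALS9, which encodes galectin-9, from 145 ± 0.166 to 2.83 ± 1.10, and SLFN11, a gene that sensitises cells to DNA damage, from 1505 ± 140 to 297 ± 42.2 (SD, n = 2 each). The 3 NR4A and the 4 listed KLF genes were each over 2-fold higher in EV replicate 1 than in EV replicate 2. NR4A1 stood at 7955 and 17.6 in the EV libraries and KLF4 at 1449 and 59.6.

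The 2 EV libraries lay over 2-fold apart in more listed genes than the 2 overexpressing libraries. Sampling noise is argued against, since among 360 genes with a mean normalized count of at least 500 the share was still 47.2% in EV and 3.89% in overexpressing cells. EV replicate 2 might hold overexpressing cells: the 181 genes that fell would need a median share of 57.2%, yet 31 genes with 0 counts in EV replicate 1 reached in EV replicate 2 only 3.996% of the overexpressing level, pooled. Selection of the listed genes can hide genes that obey such a mixture but cannot create these 31. A graded response to PHF19, which was higher in EV replicate 2, stays open: EV replicate 2 was closer to overexpressing cells in 74.6% of the genes that fell (exact 95% interval 67.6 to 80.8) but in 53.6% of those that rose (43.9 to 63.0), and with 1 library at each level it cannot be told apart from handling of EV replicate 1, which was not tested.

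Genes named ZNF with a number, mostly zinc finger genes of chromosome 19, were higher more often than other listed genes: 19 of 28 (67.9%) against 35.6% of the rest. Of the 28, 5 passed: ZNF43, ZNF257, ZNF613 and ZNF506 rose and ZNF160 fell at the adjusted p of 0.05. Expression level is argued against, because 37.6% of the other listed genes were higher when weighted to the same mean expression (95% interval 34.4 to 40.8, counting genes as independent). A shift of chromosome 19 as a whole is argued against too: 32.3% of its 62 other listed genes were higher, with an exact 95% interval of 20.9 to 45.3, below the 83.3% of its 18 ZNF genes. Reads shared between these related genes were not tested and may contribute, and because the family was picked after its values were seen, no p-value is given for it and a change of the family as a whole stays open.

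Neighbouring listed genes changed in the same direction in 697 of 1207 pairs, where permuted directions gave 648 on average (permutation p = 0.0012). The longest run was 21 listed genes in a row, all lower, on chromosome 20 from ASIP to FAM210B (34194569 to 56368663). Genes outside the table are not counted in a run, so it is no unbroken block of lower genes. Of the 21, 8 were past 0.05, 19 were lower than EV replicate 2 as well and 11 were over 2-fold lower than it. EV replicate 1 alone is argued against, since the excess stayed with directions taken against EV replicate 2 (permutation p = 0.0036). For neighbours over 1 Mb apart the excess was gone (316 of 611 pairs, permutation p = 0.854). Local gene clusters would give this, for example the 13 listed genes in a row, all lower, from HSPA1A to HLA-DPB1 on chromosome 6. That run includes the near-identical HLA-DR beta genes. Overlapping, antisense and near-identical genes, whose counts are uncertain, were kept in the pairs, and their share of the excess was not tested. A copy number difference over longer stretches was not tested further and no biological explanation was tested.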
